A study of Homo sapiens with 2 samples.

How the data were processed

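RNA-seq was carried out on 2 libraries of human cells labelled HAL-01, 1 labelled Control and 1 labelled AG. Per the labels, total RNA was extracted with Trizol and libraries were made with a stranded TruSeq mRNA kit. Per the series design, the AG culture received 0.8 mM 1,5-AG for 24 h, and how the Control culture was treated is not given in the sources used here.

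The deposited values are FPKM per gene, made by the authors. Trimmomatic, HISAT2, Cufflinks, HTSeq and the build hg38 are named per the submitters' processing notes, without versions. The gene annotation release, the strand setting and any filter are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies therefore cannot be told apart, and genes such as RPL7A and FTH1 are treated as uncertain. FPKM divides by the library total, so a change in a few abundant genes shifts all others.

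Depth was recovered from the deposited FPKM. For genes with a single transcript in GENCODE 29, FPKM times exon length came out as whole fragments, within 0.01, in 88.4% of 5315 genes of Control and 88.1% of 5259 genes of AG. The implied totals were 16240451 and 14857372 fragments. Listed genes held 43.2% and 43.8% of these totals, and the remaining fragments were not analysed here. The pair of whole fragment numbers behind a gene was recovered for 99.3% of expressed genes. The ratio of AG to Control FPKM was given an exact 95% Clopper-Pearson interval from this pair. Fragments are not independent molecules, so the intervals cover counting error only.

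Genes were matched by Ensembl ID, and 97.1% of 16145 IDs were in GENCODE 29, whose GRCh38 coordinates are the ones given. The files list no zeros, and abundant genes were listed in 1 library only, so such genes were neither set to 0 nor compared. Other genes that most cells express, among them 11 of the 25 housekeeping genes and 10 of the 17 glycolysis genes, were not analysed here in either library. A gene without a value is therefore not read as unexpressed, and list medians describe only the members analysed. Values near 0 were also listed for ALDOA of the glycolysis list and NUSAP1 of the G2/M list. A listed value near 0 can therefore also reflect reads that were not counted. Expressed genes were those listed in both libraries with a mean of at least 1 FPKM. The change was log2((AG FPKM + 1)/(Control FPKM + 1)), whose pseudocount understates the change of low genes, and a separate plain ratio of FPKM is given with its interval. No test between conditions was possible with 1 library per group, and no count model was fitted to compare the conditions. The counting bounds of list medians are the 95% range over 1000 Poisson draws of each gene's fragments.

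The rule for named genes, the gene lists and the alternatives, apart from those named as later in the closing section, were set before the data were examined. Named were the 15 genes with the largest and the 15 with the smallest log2 ratio among those with a mean of at least 5 FPKM, and the 2 highest and 2 lowest expressed members of each list. In the sugar metabolism and antioxidant lists any member could be named. The values of some genes that this rule names are not reported here. There were 30 lists of pathways and programmes and 5 of cell type markers, and a member counted as higher or lower from 1.5-fold. The median log2 ratio of a list with at least 3 expressed members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The two-sided share of random lists as far out was adjusted by the Benjamini-Hochberg method over 28 lists. Further lists, used in the closing section only, were of mature monocyte and macrophage genes, progenitor and promyelocyte genes, B lineage genes, and PPAR, retinoic acid and LXR targets.

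The steps were tested on simulated data for the comparison of AG with Control, over 5492 genes of which 200 were changed 4-fold, that is by 2 on the log2 scale. The simulation placed 99.5% of the changed and 0.51% of the unchanged genes past 2-fold, and the counting intervals covered the true ratio for 95.6% of genes. The simulated counts held counting error only, with no spread between cultures, so these values are not error rates for the real libraries. Changed genes were drawn from those with a mean of at least 5 FPKM. The intervals used the simulated counts themselves, not recovered pairs. The alternatives were pseudocounts of 0.1 and 5 FPKM, other filters on low values, rescaling to a common total, scaling by the median of ratios, a 1.5-fold threshold and leaving out genes of uncertain assignment. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.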

Results

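RNA-seq gene expression was measured in cells labelled HAL-01, a human cell line described in the labels as pre-B acute lymphoblastic leukaemia. There were 2 libraries, 1 of a culture labelled Control and 1 of a culture labelled AG. The AG culture had received 0.8 mM 1,5-AG (1,5-anhydroglucitol, a glucose analogue) for 24 h. With 1 library per group, none of the differences below has a replicate check, and no p-value is given. The deposited values are FPKM (fragments scaled by gene length and library total). The steps between low values implied totals of 16240451 fragments for Control and 14857372 for AG, a ratio of 1.09. Control listed 13342 genes and AG listed 13351, with no zeros, and 10548 genes were listed in both. Genes listed in 1 library only were left out of the comparison, because a missing gene had no value rather than a value of 0.

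The lineage genes did not follow the label in either library. The genes of B cell precursors named here were close to 0. CD79A, a component of the B cell receptor, had 0.275 FPKM in Control and 0.351 in AG, and EBF1, a B lineage transcription factor, had 0.194 and 0.0531. RAG1, IGLL1 and MME were listed in Control only, at 0.102, 0.137 and 0.00624 FPKM. Genes of granulocytes and monocytes were abundant. CTSG, the granule protease cathepsin G, had 743 FPKM in Control and 194 in AG. LYZ, which encodes lysozyme, had 75.6 and 104, S100A9 had 66.3 and 131, and ELANE, neutrophil elastase, had 47.6 and 41.8. Of the 7 listed members of the monocyte and granulocyte list, 4 were above 10 FPKM in both libraries. HLF, the partner of TCF3 in the fusion that defines the HAL-01 line, was listed in Control only, at 0.00909 FPKM. These B lineage genes were chosen after their values were seen, and not all members of their list are reported. The cells are therefore named by their label throughout.

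**Figure D1:**
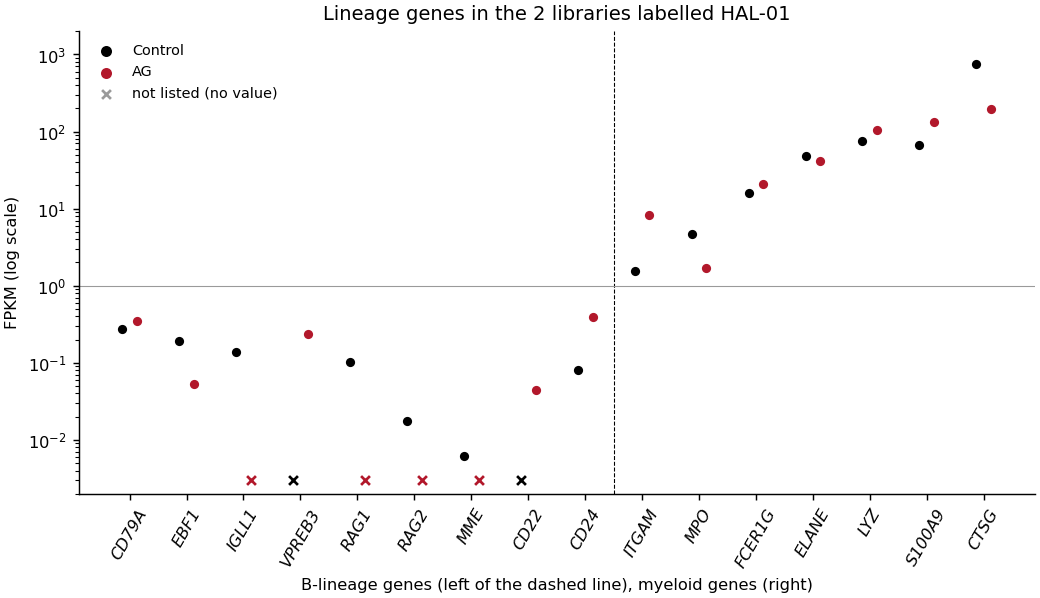
FPKM on a log scale of 9 B lineage genes and 7 myeloid genes in the Control library (black) and the AG library (red), with a cross where a gene was not listed and so had no value. The B lineage genes drawn lie below 1 FPKM, and CTSG reaches 743 FPKM in Control.

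The design asks how gene expression in the library labelled AG differed from that in Control. Among 5528 genes listed in both with a mean of at least 1 FPKM, most differed little. The values on the log2(FPKM + 1) scale had a Pearson r of 0.977 across genes, which are not independent replicates, and 97.9% of genes were within 2-fold. On that scale 65 genes were at least 2-fold higher in AG and 49 were at least 2-fold lower, with a median log2 ratio of -0.03. Of the 65 higher genes, 27 had a mean of at least 5 FPKM, 41 were protein-coding and 49 had a 95% counting interval of the FPKM ratio that excluded 1. Of the 49 lower genes, these numbers were 5, 18 and 28. The counting intervals cover counting error only, not the spread between cultures. Except where stated, these intervals and those of the genes named below were not adjusted for the choice of genes by their ratio. They can therefore be too narrow. Fragment pairs, and so intervals, were recovered for 64 of the 65 higher and 47 of the 49 lower genes. A pseudocount of 0.1 FPKM gave 136 higher and 129 lower genes, and one of 5 FPKM gave 17 and 5.

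Among genes with a mean of at least 5 FPKM, those highest in AG relative to Control were led by FGR and CD1D. FGR, a SRC family kinase of myeloid cells, had 1.18 FPKM in Control and 29.3 in AG, a ratio of 24.7 (95% counting interval 19.3 to 32.2). CD1D, which presents lipid antigens, had 3.59 and 22.7, a ratio of 6.31 (5.52 to 7.24). PLIN2, a coat protein of lipid droplets, had 7.41 and 31.2, a ratio of 4.21 (3.85 to 4.61). HK3, a hexokinase of myeloid cells, had 4.68 and 18.8, a ratio of 4.02 (3.49 to 4.64). TREM2, a receptor of macrophages, had 49.6 and 117, and SAMHD1, a dNTP hydrolase, had 32.9 and 76.6. The others of the 15 were TMEM160, NTSR1, RPL7A, KCTD12, CAMK2D, MYO10, SMPDL3A, MCEMP1 and SEMA4C, with ratios from 2.40 for MCEMP1 to 4.45 for TMEM160. RPL7A, at 12.8 and 40.2 FPKM, is uncertain because ribosomal protein genes have many pseudogenes with which reads can be shared.

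Among genes with a mean of at least 5 FPKM, those lowest in AG relative to Control were led by CST7 and CTSG. CST7, the protease inhibitor cystatin F, had 9.47 FPKM in Control and 1.44 in AG, a ratio of 0.152 (95% counting interval 0.0886 to 0.246). CTSG had a ratio of 0.261 (0.252 to 0.270). MLC1, a membrane protein, had 199 and 76.2 FPKM, a ratio of 0.382 (0.369 to 0.396). TXNIP, an arrestin family protein that restrains glucose uptake, had 76.8 and 31.1, a ratio of 0.405 (0.383 to 0.429). BCL2, which blocks apoptosis, had 21.9 and 11.9, a ratio of 0.542 (0.514 to 0.570). SLC39A10, a zinc transporter, had 19.8 and 10.9, and NAPRT, an enzyme of NAD synthesis, had 11.2 and 5.43. The remaining 8 of the 15 were RFX8, INKA1, the non-coding genes AC007907.1, AC018553.1, LINC00623 and AL391832.3, and the microRNA genes MIR30C1 and MIR25. Their ratios ran from 0.424 for RFX8 to 0.531 for INKA1. The microRNA genes rested on 12 and 37 fragments in Control and lie within longer genes, so their reads cannot be told from those of the host, and the interval of MIR30C1 (0.126 to 1.39) includes 1.

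In GRCh38 coordinates of GENCODE 29, the protein-coding genes FGR (ENSG00000000938) and CD1D (ENSG00000158473) lie on chromosome 1, at 27612064 to 27635277 on the minus strand and at 158179947 to 158184896 on the plus strand. PLIN2 (ENSG00000147872) lies on chromosome 9 at 19108375 to 19149290 and HK3 (ENSG00000160883) on chromosome 5 at 176880869 to 176899332, both on the minus strand. CTSG (ENSG00000100448) lies on chromosome 14 at 24573522 to 24576260, MLC1 (ENSG00000100427) on chromosome 22 at 50059391 to 50085902 and TXNIP (ENSG00000265972) on chromosome 1 at 145992435 to 145996600, all on the minus strand. Each value is an FPKM for the whole gene under the submitters' annotation, whose gene lengths can differ from those of GENCODE 29.

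**Figure D2:**
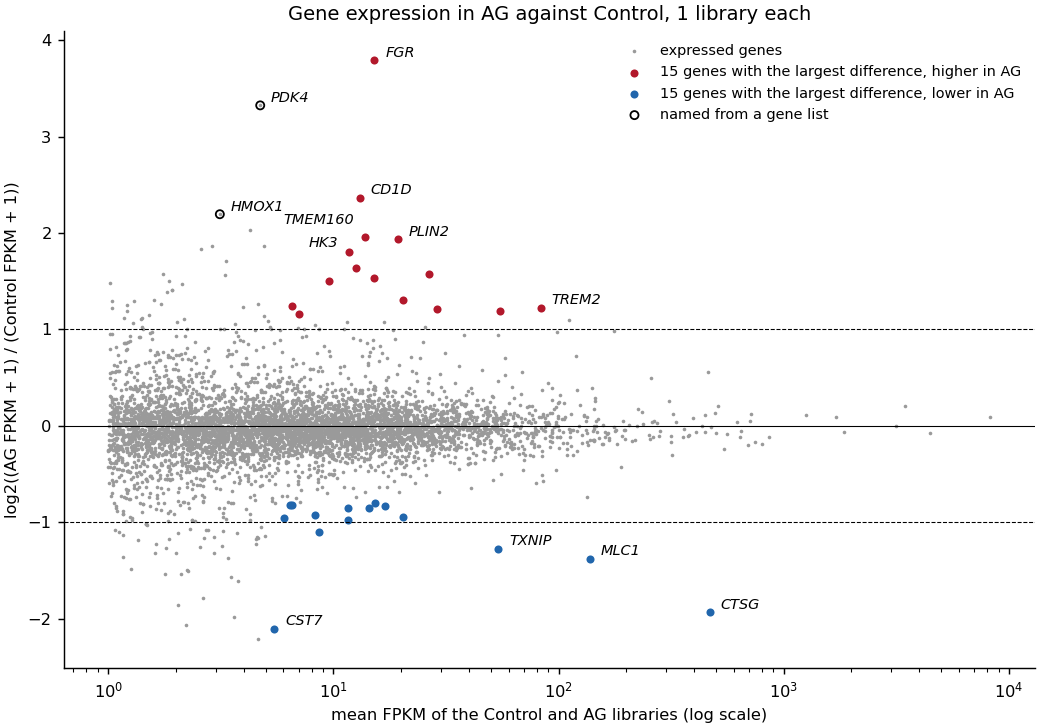
Mean FPKM of both libraries on a log scale against the log2 ratio of AG over Control for 5528 expressed genes (grey), with the 15 genes highest (red) and the 15 lowest (blue) in AG relative to Control among those with a mean of at least 5 FPKM, and dashed lines at 2-fold. FGR and CD1D stand highest among the red points, CST7 and CTSG lowest among the blue, and PDK4 and HMOX1 (open circles) were named from gene lists.

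The members of the sugar metabolism lists that were analysed showed no common change in either direction. All 5 expressed glycolysis genes were within 1.5-fold, with a median log2 ratio of 0.08, at percentile 88.2 of 10000 random lists matched on expression (median 0.1271, percentile 95.82 without a filter on low values). LDHA, lactate dehydrogenase, had 10.7 FPKM in Control and 14.3 in AG, and HK2, a hexokinase, had 7.14 and 5.97. The hexokinase HK3, at 4.68 and 18.8, was not on this list. Of the 17 genes of the glycolysis list 10, GAPDH among them, were not analysed here in either library, so these values do not speak for the pathway as a whole. Of 10 expressed genes of glucose, lactate and pyruvate transport and glycolytic regulation, 1 was higher by at least 1.5-fold, 1 was lower and 8 were within 1.5-fold (median -0.02, mean 0.16, percentile 53.4). The higher one was PDK4, a kinase that inhibits pyruvate dehydrogenase. It rested on 3 fragments in Control and 636 in AG, or 0.0407 and 9.42 FPKM, a ratio of 232 (95% counting interval 78.9 to 1127). The lower one was TXNIP. ARRDC4, a relative of TXNIP, had 3.14 and 2.17 FPKM, and SLC2A1, the glucose transporter GLUT1, had 51.6 and 42.5. The pentose phosphate list had 2 expressed members, both within 1.5-fold (median -0.07). The polyol and fructose list also had 2, SORD at 4.38 and 4.02 and ADPGK at 26.1 and 28.0 (median 0.00).

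The TCA cycle list was slightly higher in AG. All 11 expressed TCA cycle genes were within 1.5-fold and 9 were above 0 (median 0.14, percentile 99.5, adjusted share 0.039), with SDHB at 35.9 FPKM in Control and 42.1 in AG. Of 17 nuclear-encoded oxidative phosphorylation genes, 16 were within 1.5-fold and 14 were above 0 (median 0.06, percentile 96.5). The exception, NDUFS3, had 0.984 and 2.33 FPKM. The 6 mitochondrially encoded mRNAs were all within 1.5-fold (median 0.05, percentile 87.0). The adjusted share is the Benjamini-Hochberg adjusted, two-sided share of random lists as far out, over 28 lists. It describes these 2 libraries and is not a p-value for the treatment.

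The genes of sterol and fatty acid synthesis were higher in AG as a group. All 12 expressed members were above 0 and 3 were at least 1.5-fold higher (median 0.36, percentile 100, adjusted share 0.0056). SCD, the stearoyl-CoA desaturase, had 118 FPKM in Control and 235 in AG, a ratio of 1.98 (95% counting interval 1.93 to 2.03). STARD4, a sterol transporter, had 9.84 and 16.9, and the third gene, SREBF1, a regulator of lipid synthesis chosen after its value was seen, had 16.5 and 27.7. FDFT1, squalene synthase, differed least, with 6.90 and 7.74.

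The unfolded protein, integrated stress and immediate early lists were also higher, and the heat shock list was not outside the range of random lists. All 6 expressed genes of the unfolded protein response were above 0 and 1 was at least 1.5-fold higher (median 0.35, percentile 99.9, adjusted share 0.010). That gene was HERPUD1, which acts in degradation of misfolded proteins, at 10.2 and 19.7 FPKM, and CANX, a chaperone, had 5.64 and 7.71. Of 8 targets of the integrated stress response, 7 were above 0 and 1 was at least 1.5-fold higher (median 0.18, percentile 99.3, adjusted share 0.048). It was CEBPB, a transcription factor of myeloid cells and of stress, at 4.25 and 9.63 FPKM. The 6 heat shock genes were within 1.5-fold (median 0.08, percentile 92.1). Of 6 immediate early and MAPK response genes, 5 were above 0 and 1 was at least 1.5-fold higher (median 0.40, percentile 99.9, adjusted share 0.010). Without a filter on low values the median was 0.1358, at percentile 99.92. FOS had 6.78 and 12.3 FPKM and EGR1 had 1.85 and 3.07, and MYC was the exception at 48.5 and 36.8.

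The antioxidant list went both ways. Of 13 expressed members, 2 were at least 1.5-fold higher, 2 were at least 1.5-fold lower and 9 were within 1.5-fold, and the median (-0.03, percentile 53.03) and the mean (0.14) differed in sign. HMOX1, haem oxygenase, had 0.481 FPKM in Control and 5.78 in AG, a ratio of 12.02 (95% counting interval 7.51 to 20.4). FTH1, the ferritin heavy chain, had 10.4 and 23.0 and is uncertain because it has many pseudogenes. CAT, catalase, had 167 and 99.9 FPKM, a ratio of 0.599 (0.579 to 0.619), and SQSTM1, an autophagy receptor, had 2.32 and 0.974. CYBB, the catalytic subunit of the phagocyte NADPH oxidase and the single expressed member of its list, had 1.25 and 2.74 FPKM (log2 ratio 0.73, and 0.3076 with a pseudocount of 5 FPKM).

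The genes of G1/S and DNA replication were slightly lower in AG. All 12 expressed G1/S genes were within 1.5-fold and 11 were below 0 (median -0.23, percentile 0.020, adjusted share 0.0075), with CDT1, a replication licensing factor, at 42.1 FPKM in Control and 30.5 in AG and MCM5, a helicase subunit, at 52.3 and 40.9. All 11 G2/M genes were below 0 and within 1.5-fold, but the list's adjusted share was not under 0.05 (median -0.15, percentile 1.46, adjusted share 0.085), with BUB1 at 38.4 and 32.9. With a pseudocount of 5 FPKM the G2/M median was -0.0961, at percentile 4.64. Of 3 replication-dependent histone genes, 2 were at least 1.5-fold lower (median -0.60, percentile 0.27, adjusted share 0.029), and without a filter on low values the median was -0.1674, at percentile 3.52. Histone mRNA mostly lacks poly(A) tails, so its level in an mRNA library is uncertain. H1-2 had 4.72 and 1.93 FPKM.

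Myeloid genes moved apart from one another. Of 6 expressed members of the monocyte and granulocyte list, 2 were at least 1.5-fold higher, 1 was lower and 3 were within 1.5-fold (median 0.41, percentile 99.97, adjusted share 0.0075). ITGAM, the integrin CD11b of mature myeloid cells, had 1.55 FPKM in Control and 8.30 in AG, a ratio of 5.36 (95% counting interval 4.47 to 6.46), and S100A9 had a ratio of 1.98 (1.80 to 2.19). MPO, the granule enzyme myeloperoxidase, had 4.75 and 1.70, a ratio of 0.358 (0.278 to 0.456). Of 8 genes of the TCF3-HLF programme, 2 were at least 1.5-fold lower and 6 were within 1.5-fold (median -0.18, percentile 1.47, adjusted share 0.085), and without a filter on low values the median was -0.0815, at percentile 14.21. These 2 were ANXA8, at 4.47 and 1.45 FPKM, and BCL2. Of 5 genes of B cell identity, 1 was lower, HLA-DRA at 1.68 and 0.487 FPKM (median -0.14, percentile 16.0). Of 2 T and NK cell markers, NKG7 was lower at 17.2 and 10.3 FPKM, and CD4, which monocytes also express, had 54.9 and 61.2. The stromal list had 1 expressed member, VIM, at 8.51 and 8.52 FPKM, and the lists of mature B and plasma cells and of erythroid cells had 0.

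The other lists lay in neither outer 2.5% of the random lists at the settings used. Of 6 NF-kB targets 2 were at least 1.5-fold higher (median 0.15, percentile 97.1; among genes with a mean of at least 5 FPKM 0.4233, percentile 99.81), TNFAIP2 at 23.1 FPKM in Control and 39.8 in AG and NFKBIE at 12.1 and 19.9. The 4 hypoxia genes were within 1.5-fold (median 0.22, percentile 95.6; with a pseudocount of 5 FPKM 0.0892, percentile 91.92), with P4HA1 at 18.7 and 27.8. Of 9 autophagy and lysosome genes CTSD was higher at 7.08 and 12.3 FPKM and SQSTM1 was lower (median 0.08, percentile 92.5). Of 9 apoptosis regulators BCL2 was lower and 8 were within 1.5-fold (median 0.00, percentile 60.6). Of 23 ribosomal protein genes 22 were within 1.5-fold and 17 were below 0 (median -0.08, mean 0.00, percentile 16.98), with RPL7A the exception. All members were within 1.5-fold in the lists of one-carbon and nucleotide synthesis (median 0.05, percentile 86.1), interferon-stimulated genes (0.02, percentile 64.2), MYC and ribosome biogenesis (-0.01, percentile 56.3), insulin and FOXO signalling (-0.05, percentile 42.0) and p53 targets (-0.05, percentile 36.4). The 14 housekeeping genes, as a reference, had a median of 0.01 (percentile 74.5).

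**Figure D3:**
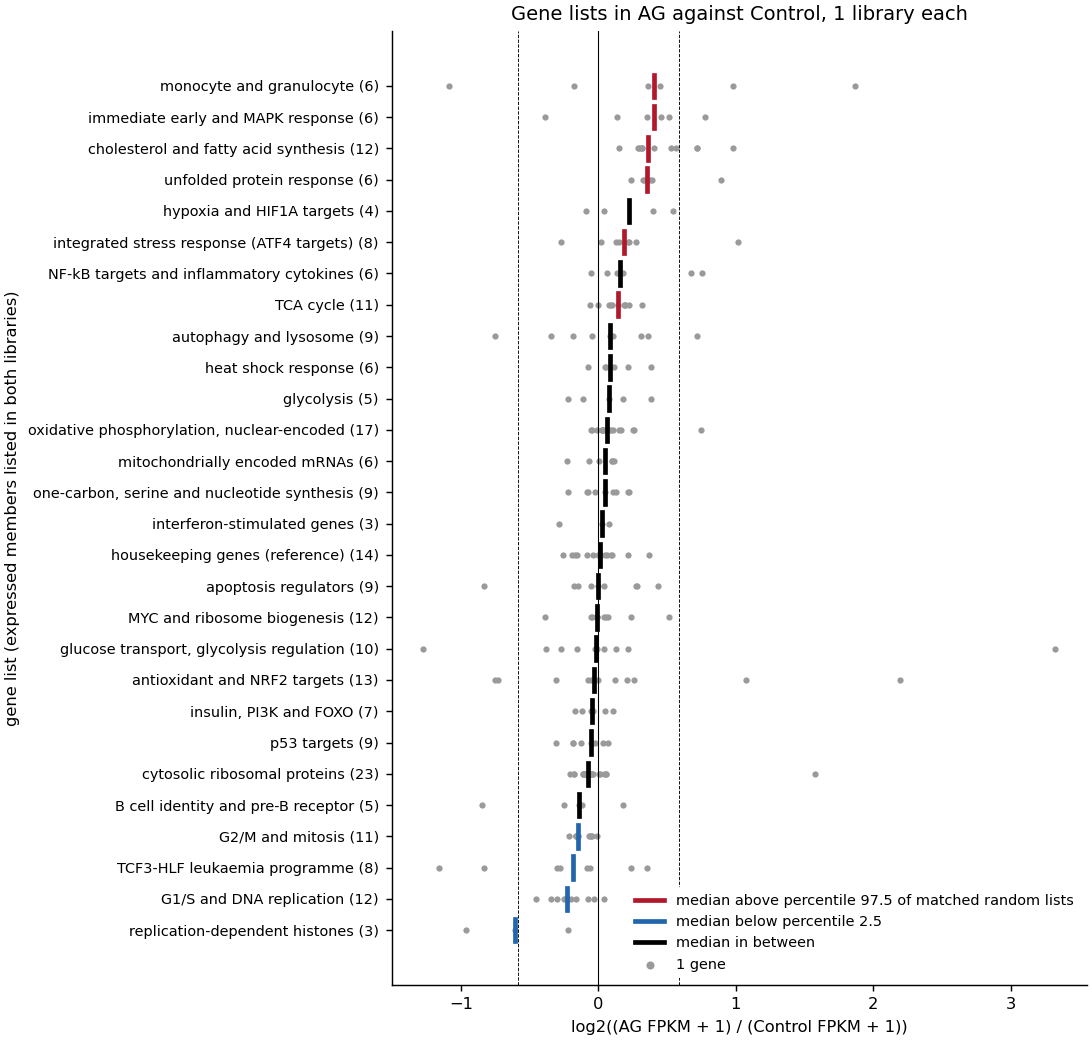
Log2 ratio of AG over Control for each expressed member (grey points) of 28 gene lists, with the list median as a bar, red in the top 2.5% and blue in the bottom 2.5% of matched random lists, and dashed lines at 1.5-fold. The bars run from -0.60 for the histone list to 0.41 for the monocyte and granulocyte list.

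Of 28 lists with at least 3 expressed members, 6 lay in the top 2.5% of the random lists and 4 in the bottom 2.5%, and 8 had an adjusted share under 0.05. If genes moved independently, 1.4 lists would lie outside. Genes of a list can move together and some lists share genes, such as BCL2. The number to be found between any 2 cultures is therefore not known. With a single culture per condition, none of these differences can be assigned to 1,5-AG rather than to another difference between the cultures.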

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

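The tests of gene identity, mixed cells, the HLF level, depth or scaling, counting error and the number of cultures below were chosen only after the result was seen. The tests on further B lineage genes and on GC content and length were set beforehand.

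Genes listed in 1 library only stood outside the comparison. Of genes at 5 FPKM or more, 87 were listed only in AG and 16 only in Control. The highest were the pseudogene RPL7P9 at 243 FPKM, RPL28 at 90.7 and DDX5 at 88.5 in AG, and AL603839.2 at 30.8 in Control.

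Both libraries labelled HAL-01 held abundant myeloid transcripts, with most listed B lineage transcripts near 0. A shift of gene IDs against values is argued against by the whole fragment numbers at each gene's own exon length, in 88.06% of single-transcript genes in the lower library. A sizeable share of pre-B cells would raise the pre-B genes, whose listed values had a median of at most 0.237 FPKM. Of 9 such genes, 7 were listed in Control and 5 in AG. They also define the pattern, so this median restates it and adds no separate evidence. RNA of another, myeloid-like cell line under the label is a candidate explanation. Further B lineage genes had medians of 0.129 FPKM in Control and 0.173 in AG, but only 3 and 5 of 15 were listed. AFF3 had 4.91 and 4.81, and BANK1, listed in AG only, had 1.45, while the other listed genes were lower than these. HAL-01 cells that lost their B cell programme would also give low values, so these medians do not tell such explanations apart. HAL-01 cells that lost their B cell programme but kept and transcribed the TCF3-HLF fusion stay open in both libraries. In Control HLF had 1 fragment and an upper 95% counting bound of 0.05196 FPKM. This goes against them only if the reads of HLF were fully counted, as the bound covers counting error alone. ALDOA of the glycolysis list also had low values, 0.515 FPKM in Control and 0.949 in AG, as did NUSAP1 of the G2/M list, 0.154 and 0.168. In AG 0 values of HLF were listed. HAL-01 cells that no longer transcribe the fusion were not tested, and genotyping was not used here.

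Mature myeloid genes were higher and CTSG and MPO lower in AG. ELANE, neutrophil elastase, did not fall with CTSG and MPO to a like degree, at 47.6 FPKM in Control and 41.8 in AG. A difference in depth or scaling, as 1 factor for every gene, cannot raise some genes and lower others. The 7 genes named below were chosen on both sides, so this outcome was fixed by their choice. The 5521 other expressed genes had a median log2 FPKM ratio of -0.0359 (95% interval -0.0434 to -0.0292). Counting error is argued against, since the counting intervals of 7 of the 7 genes FGR, ITGAM, S100A9, TREM2, MCEMP1, CTSG and MPO excluded a ratio of 1 after adjustment for their choice among 5528 expressed genes, with MPO nearest at 0.2008 to 0.6065 on the lower side and S100A9 at 1.588 to 2.486 on the higher. An effect of 1,5-AG and a chance difference between cultures, such as density or medium, cannot be told apart, because there was 1 culture per condition.

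The sterol and unfolded protein lists were higher and the G1/S list lower in AG. After a trend on GC content and exon length was removed, 3 of the 3 lists stayed in the outer 2.5% of random lists on their side, with medians of 0.38, 0.38 and -0.19. These values argue against that trend as the whole explanation. A difference in depth or scaling, as 1 factor for every gene, cannot place lists on both sides of the other genes. The lists were chosen on both sides, so this outcome was fixed by their choice. The 5498 expressed genes outside these lists had a median log2 ratio of -0.0315. It lay between the counting bounds of the G1/S median (upper -0.1692) and those of the sterol and unfolded protein medians (lowest 0.3182). A difference between the cultures other than 1,5-AG stays open here too, as it was not tested.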

How the results depend on the processing

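For lists other than the glycolysis, pentose phosphate, nuclear-encoded oxidative phosphorylation and antioxidant ones, the alternatives on filters and uncertain genes were chosen after seeing the data, as were all percentiles under them. The lists in the outer 2.5% of random lists kept the sign of their median under each alternative run, but not always its size or place. The G2/M list left the bottom 2.5% with a pseudocount of 5 FPKM (median -0.0961, percentile 4.64), without a filter (-0.1065, 5.77) and with a mean of at least 5 FPKM (-0.1065, 5.32), the TCF3-HLF list without a filter (-0.0815, 14.21) and with a mean of at least 5 FPKM (-0.0847, 18.425), and the histone list without a filter (-0.1674, 3.52). The histone median was -0.3988 with a pseudocount of 5 FPKM, and the list had no value without uncertain genes and too few members for a percentile with a mean of at least 5 FPKM. The immediate early median, 0.40, was 0.1358 without a filter, 0.1862 with a pseudocount of 5 FPKM and 0.1915 with a mean of at least 5 FPKM, where too few members were left for a percentile. The medians of the G1/S, sterol, unfolded protein, integrated stress, TCA cycle and monocyte lists moved by less than 1.5 times and these lists stayed in their outer 2.5% under each alternative run. The nuclear-encoded oxidative phosphorylation list entered the top 2.5% with a pseudocount of 5 FPKM (97.905) and without a filter (98.35), and the NF-kB list with a mean of at least 5 FPKM (median 0.4233, percentile 99.81). With a pseudocount of 5 FPKM the hypoxia median, 0.22, was 0.0892, that of B cell identity, -0.14, was -0.0919 and that of NADPH oxidases, 0.73, was 0.3076. Without a filter the last was 0.321 and that of T and NK cells, -0.27, was -0.1619. Medians near 0 changed sign in some for the polyol, interferon, housekeeping, stromal, glucose transport, apoptosis and MYC lists, at most to -0.133 for the interferon list with a mean of at least 5 FPKM, and moved by more than 1.5 times in some for the insulin, one-carbon, p53, antioxidant, pentose phosphate, ribosomal and mitochondrially encoded lists, so no direction is read from them. At a threshold of 1.5-fold instead of 2-fold, 199 genes were higher and 184 lower in AG. The numbers of genes at least 2-fold higher and lower in AG, 65 and 49, depended on how low values were treated. They were 136 and 129 with a pseudocount of 0.1 FPKM and 17 and 5 with one of 5 FPKM. With a mean of at least 5 FPKM they were 27 and 5, and with each library rescaled to a common total 127 and 129. Rescaling multiplies the values, so that the pseudocount of 1 weighs less. The median of expressed genes, -0.03, was -0.0351 and -0.0188 with these pseudocounts, -0.0119 without a filter, -0.0481 after rescaling and -0.0072 after scaling by the median of ratios. The glycolysis median, 0.08, was 0.1271 without a filter (percentile 95.82) and 0.103 after scaling by the median of ratios; the cause of these and the list changes was not tested. Of the 15 named genes each way, 7 higher and 3 lower stayed named with a mean of at least 1 FPKM, where genes with few fragments enter. Depth left 49 of the 65 higher and 28 of the 49 lower genes with an unadjusted counting interval that excluded 1. The robust SD of the log2 ratio, 0.25 from 1 FPKM and 0.16 from 20 FPKM, holds both counting error and differences between the cultures, which were not separated.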

Other observations

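The tests on lists below were set before the values of their genes were seen, but the patterns that led to them came from the same 2 libraries, so each remains a hypothesis.

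Further genes of monocytes and macrophages were higher in AG. Of 48 such genes that had not been looked at, 12 were expressed and listed in both libraries, 11 were above 0 and 2 were at least 1.5-fold higher (median log2 ratio 0.36). CD300A, an inhibitory receptor of myeloid cells, had 3.17 FPKM in Control and 7.35 in AG. ITGAX, the integrin CD11c, had 3.94 and 6.17, while IRF8 was abundant and close in both, at 189 and 196. IL1RN was the exception, at 4.41 and 3.45. These genes were chosen for naming after their values were seen.

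A shift towards a mature myeloid programme is one hypothesis for these values: the list's median lay at percentile 100 of matched random lists. Its counterpart, a lower progenitor and promyelocyte programme, had a median of -0.26 at percentile 1.725, but over only 3 expressed members of 15. These were CDK6 at 50.1 FPKM in Control and 31.7 in AG, STMN1 at 92.3 and 76.9 and P4HB at 95.8 and 98.4. CDK6 and STMN1 also go with cell division, and the G1/S list was lower in AG, so this second result may be no more than that. Neither test separates 1,5-AG from another difference between the 2 cultures.

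PDK4, PLIN2 and CD1D, all higher in AG, are known to respond to lipid-sensing nuclear receptors. The hypothesis that PPAR targets were higher together was tested on 29 further targets, of which 8 were expressed. Their median log2 ratio was 0.19, at percentile 99.64, with 7 above 0 and 1 at least 1.5-fold higher, SLC25A20, a carnitine carrier, at 11.9 FPKM in Control and 24.8 in AG. HILPDA went the other way, at 6.01 and 4.29. Most of these targets act in mitochondrial fatty acid oxidation, and the TCA cycle list was higher too, so a general shift of mitochondrial genes may account for part of it. Retinoic acid targets and LXR targets could not be placed, with 2 expressed members each. RARA had 4.71 and 9.79 FPKM and CYP26B1 had 1.87 and 3.19, and of the LXR targets LPCAT3 had 4.33 and 6.02 and MYLIP had 10.1 and 12.01.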
